A study of Oryza sativa with 60 samples.

How the data were processed

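Anthers of wild-type Kitaake rice grown in a greenhouse were collected at 10 lengths, and total RNA of 20 to 30 anthers per sample was used, per the labels. Each length had 3 biological replicates, and 60 libraries were deposited: 30 of polyadenylated RNA, made with a directional kit, and 30 of small RNA. Groups were taken from the sample titles alone, and replicate numbers are those of the titles. The submitters' processing notes name HISAT2 2.1.1, StringTie 2.1.4, cutadapt 3.0, FastQC 0.12 and Bowtie2 2.5.2.

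For mRNA the authors deposited FPKM, scaled by transcript length and mapped fragments, with 48494 transcript entries per library named by gene ID only. FPKM were summed per gene ID, which gave 35594 genes, 28505 of them with 1 transcript entry. Depth was not given, and whole read numbers could not be recovered from the values, so no count model was used and no counting interval is given. For small RNA the authors deposited raw read counts per mature miRNA. Each library had 2 tables, whose counts were equal in 30 of 30 libraries, and those marked as all reads were used. Reads assigned to no miRNA were listed in 26 libraries and were not analysed here beyond their share. The other 4 libraries, labelled 0.4 mm replicate 3 and 1.0 mm replicates 1, 2 and 3, named another reference set and lacked that entry. Of the 582 entries, 81 had no miRBase number and 72 were merged names of several family members. An entry named miR2275c occurred with and without a miRBase number, and the numbered one is meant unless stated.

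Levels of miRNAs are CPM, the count of an entry scaled to the total of the miRNA reads of a library. Fold changes come from fits with TMM scaling and can differ from the ratio of these means. Total miRNA counts were 7527 to 584897 per library, so a floor of 3 counts corresponded to 5.13 to 399 CPM. Where listed, miRNA reads were 0.675% to 2.51% of all reads in a table (Wilson intervals at 95% were at most 0.744% to 0.778% in the shallowest library). Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

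For mRNA, genes with at least 1 FPKM in at least 3 libraries were kept (26091), and log2(FPKM + 1) was fitted in limma 3.58.1 (lmFit, eBayes with trend) with the 10 sizes as 1 factor. For miRNA, edgeR 4.0.16 (filterByExpr, TMM, glmQLFit, glmQLFTest) was used in the same design, which kept 371 entries holding 99.8% of the miRNA reads. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1, and for the test over all sizes at the adjusted p alone. The comparisons were 1.0 against 0.4 mm, 1.6 against 1.0 mm and 2.5 against 1.6 mm, the 9 steps between adjacent sizes for mRNA, and the test over all sizes. SE of miRNA log2 fold changes were derived from the F statistic. Lists of miRNA families fixed in advance were tested with fry on log2 CPM, with adjustment over 30 tests (10 lists, 3 comparisons). fry asks whether the members move, on balance, one way, and does not compare them with other miRNAs. The lists were miR2118, miR2275, miR390, phase change (miR156, miR172, miR529, miR535), miR159 with miR319, auxin (miR160, miR167, miR393), meristem and leaf (miR164, miR166, miR171, miR394, miR396), miR162 with miR168, nutrient and copper (miR395, miR397, miR398, miR399, miR408, miR528, miR827) and miR444.

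The order of small RNA groups was compared with that of mRNA by Pearson and Spearman correlation of 45 distances (1 minus the correlation of group mean profiles), with 100000 one-sided permutations of the group labels, for each of 10 rotations. Sizes were read from the deposited names for this check only, with a bare digit in a name taken as the digit after the decimal point.

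Names of genes could not be had: 0 of the Kitaake IDs occur in the reference table, so the 99 entries of the 9 gene lists fixed in advance matched 0 genes and were not tested. For that reason at most 2 rising and 2 falling IDs are given per comparison, those with the largest change among called genes with a mean of at least 10 FPKM in the higher group and no overlap between the groups. Named miRNAs are the most abundant member of each listed family, the 3 most abundant of miR2118 and miR2275, and the 5 largest rises and 5 largest falls among called entries with at least 10 CPM in the higher group. The comparisons, the tests, the rule for named miRNAs, the lists and most alternatives were chosen before the data were examined. For genes, the rule fixed in advance covered named genes only. The limit of 2 rising and 2 falling IDs was set once no names could be had.

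Alternatives fixed in advance were a pseudocount of 0.1, no filter, quantile normalization, the replicate number as a block, a fit on the compared sizes alone, adjusted p alone, each library left out in turn, and for miRNA also DESeq2 1.42.0, library totals without TMM, counts summed per family, a model term for the 4 libraries of the other reference set, and their removal. Chosen after seeing the data were the fry test for change in either direction, a rescaling of FPKM to TPM, fits without 2 doubted mRNA libraries (1.4 mm replicate 1 and 2.5 mm replicate 3) or without 4 doubted small RNA libraries (labelled 1.2 mm replicate 2, 1.4 mm replicates 1 and 2, and 2.5 mm replicate 1), and alternatives of the label check and of the lists.

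The tests were tested on simulated data made from these libraries. A call in these simulations was an adjusted p under 0.05 alone, without the limit on the fold change, so the rates are not those of the calls reported below. With log2 changes of 1 and 2 in 200 genes, limma called 32.5% and 95.5% of them, and false calls were 5.8% and 4.02% of its calls. With log2 changes of 1, 2 and 4 in 100 miRNAs, edgeR called 0, 12 and 89 of them, and false calls were at most 4.3% of its calls. Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9) and R 4.3.3 (statmod 1.5.0) were used.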

Results

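Anthers of wild-type Kitaake rice, a japonica cultivar used for transformation, were sampled at 10 lengths between 0.4 and 2.5 mm, with 3 biological replicates at each length. Polyadenylated RNA and small RNA were sequenced, which gave 30 mRNA libraries and 30 small RNA libraries. The deposited mRNA tables held FPKM for 35594 gene IDs of the Kitaake annotation, with no gene names and no positions, and the depth behind the FPKM is unknown. The genome build is not given in the sources used here. Between 17391 and 21213 genes per library reached 1 FPKM. The small RNA tables held read counts for mature miRNAs, given below as CPM, counts scaled to the total of miRNA reads of a library. Total miRNA counts ranged from 7527, in the library labelled 2.5 mm replicate 1, to 584897, in the library labelled 1.4 mm replicate 2, with a median of 227720.5. A count of 0 in a library allowed up to 5.13 CPM in the deepest library and up to 399 in the shallowest, from counting error alone.

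The titles of the small RNA libraries and the sizes carried by the names under which they were deposited differed in all 30 libraries, by the same rotation of the 10 sizes. Libraries labelled 0.4, 0.6, 0.8, 1.0, 1.2, 1.4 and 1.6 mm carried 1.0, 1.2, 1.4, 1.6, 1.8, 2.0 and 2.5 mm in those names. Libraries labelled 1.8, 2.0 and 2.5 mm carried a bare digit without a decimal point, which was read as 0.4, 0.6 and 0.8 mm. For mRNA, title and name gave the same size in 30 of 30 libraries. Small RNA groups are given here by their label, with the size in the deposited name beside it, since the sources used here do not settle which is right. The group distances compared with mRNA below followed the names more closely than the labels (Pearson's r = 0.802 against 0.120).

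The first principal component of the mRNA libraries held 42.9% of the variance and the second 18.1%. From 1.0 mm on, the group means on the first component rose with anther length, while libraries of 0.4 to 1.0 mm lay close together, 1.6 and 1.8 mm formed another group, and 2.5 mm lay farthest from the others. In 25 of the 30 libraries the closest group mean was that of their own size. The exceptions were 0.4 mm replicate 3, 0.8 mm replicate 3, 1.2 mm replicates 2 and 3, and 2.5 mm replicate 3, which correlated at r = 0.895 with the other 2.5 mm libraries and at 0.932 with 2.0 mm, across genes, which are not independent replicates. In limma, 23980 of 26091 tested genes (91.9%) differed among the 10 sizes at an adjusted p (Benjamini-Hochberg) under the limit of 0.05.

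**Figure D1:**
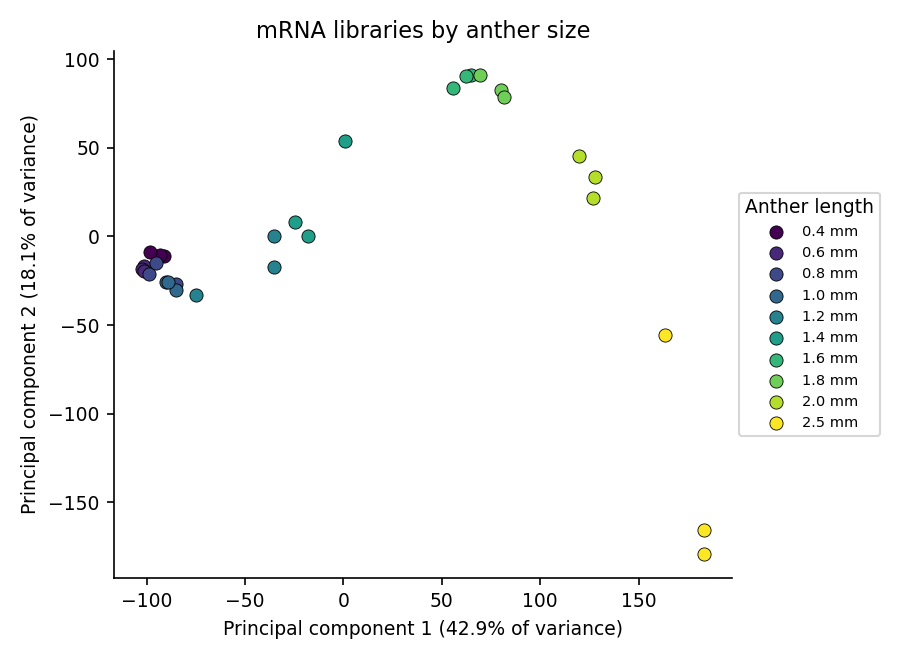
Each point is 1 mRNA library, placed by its first (horizontal) and second (vertical) principal component score of log2 FPKM, in arbitrary units, and coloured by anther length in mm. Libraries of 0.4 to 1.0 mm sit together at the left, 1.6 and 1.8 mm at the top, and 2.5 mm at the lower right, with 2.5 mm replicate 3 between the other 2.5 mm libraries and those of 2.0 mm.

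The sizes at which genes reached their highest mean were unevenly spread. Of the 23980 genes, 5605 were highest at 0.4 mm, 2520 at 0.6 mm, 1521 at 0.8 mm, 1406 at 1.0 mm, 911 at 1.2 mm, 2177 at 1.4 mm, 2119 at 1.6 mm, 1705 at 1.8 mm, 3212 at 2.0 mm and 2804 at 2.5 mm. Genes of 2.5 mm anthers were the most restricted of these by a descriptive measure: 556 of the 2804 had a mean at least 2 log2 units above that of every other size, against 95 of the 2177 genes of 1.4 mm and 75 of the 5605 genes of 0.4 mm. Anthers of 2.5 mm are also set apart from the next size by the widest gap in length of the series. With quantile normalization the number of genes highest at 2.5 mm was 4882 and that at 1.2 mm 1638. After rescaling to TPM that at 1.2 mm was 1617. Without replicate 1 of every size 964 genes were highest at 0.8 mm and 1089 at 1.8 mm, and without replicate 2 of every size 985 were highest at 0.8 mm.

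Between 0.4 and 1.0 mm, the early part of the series, 3932 genes changed, 1503 of them higher and 2429 lower at 1.0 mm. OsKitaake01g218500.v3.1 rose from 1.60 ± 0.788 to 1932 ± 421 FPKM (mean ± SD, n = 3; log2 fold change 9.56, SE 0.873, adjusted p = 2.67e-09 in limma). OsKitaake01g083800.v3.1 rose from 9.72 ± 8.18 to 5233 ± 2498 FPKM (log2 fold change 9.11, SE 0.737, adjusted p = 2.44e-10). OsKitaake03g193100.v3.1 fell from 411 ± 69.3 to 2.28 ± 0.873 FPKM (log2 fold change -7.00, SE 0.532, adjusted p = 7.14e-11). OsKitaake12g083600.v3.1 fell from 87.2 ± 12.0 FPKM at 0.4 mm to a listed value of 0 in all 3 libraries of 1.0 mm (adjusted p = 1.84e-17), for which no fold is given. The deposited files and the reference held no name for any of these IDs, so their functions are not given. The split between higher and lower genes depended on the scaling: 38.2% of the called genes were higher at 1.0 mm on the deposited FPKM and 51.2% after quantile normalization, and the median log2 fold change of all genes was -0.179 and -0.017.

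From 1.0 to 1.6 mm, the middle part, 6013 genes changed, with 3482 higher and 2531 lower at 1.6 mm. A pair of IDs with nearby numbers, OsKitaake10g024300.v3.1 and OsKitaake10g024100.v3.1, rose from 1.17 ± 0.224 to 4651 ± 247 FPKM and from 1.90 ± 0.905 to 5189 ± 959 FPKM (mean ± SD, n = 3). Their log2 fold changes were 11.07 (SE 0.85, adjusted p = 2.23e-10 in limma) and 10.83 (SE 1.18, adjusted p = 5.83e-08). OsKitaake04g309600.v3.1 fell from 8317 ± 2775 to 3.23 ± 1.72 FPKM (log2 fold change -10.96, SE 1.16, adjusted p = 3.62e-08). OsKitaake08g237700.v3.1 fell from 3316 ± 867 to 2.19 ± 1.27 FPKM (log2 fold change -10.06, SE 0.949, adjusted p = 5.61e-09). The median log2 fold change of all genes was 0.033. Among called genes, 57.9% were higher at 1.6 mm on the deposited FPKM and 51.0% after quantile normalization.

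From 1.6 to 2.5 mm, the late part, 10187 genes changed, and most of them were lower at 2.5 mm on the deposited FPKM: 7824 lower and 2363 higher. The gap in length is wider here than in the early and middle parts. Both IDs that had risen most at 1.6 mm fell again, OsKitaake10g024300.v3.1 to 2.1 ± 1.8 FPKM (log2 fold change -10.71, SE 0.85, adjusted p = 1.11e-10 in limma) and OsKitaake10g024100.v3.1 to 3.65 ± 3.25 FPKM (log2 fold change -10.39, SE 1.18, adjusted p = 7.34e-08; n = 3). OsKitaake05g246100.v3.1 rose from 0.727 ± 0.315 to 4466 ± 1512 FPKM (log2 fold change 11.29, SE 0.606, adjusted p = 4.30e-14). OsKitaake04g301800.v3.1 rose from 0.812 ± 0.655 to 4346 ± 1283 FPKM (log2 fold change 11.24, SE 0.593, adjusted p = 2.94e-14). Fewer genes reached 1 FPKM at 2.5 mm, 18411 ± 1332, than at 1.6 mm, 20646 ± 184 (mean ± SD, n = 3), and the 1000 most abundant genes held 63.9% ± 7.63 and 46.8% ± 0.85 of the FPKM. The median log2 fold change of all genes was -0.527. Quantile normalization, which gives all libraries the same distribution, moved it to -0.087 and called 7837 genes, of which 46.8% were higher, against 23.2% on the deposited FPKM. Without 2.5 mm replicate 3 the count was 12140.

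Called genes were concentrated in a few of the steps between adjacent sizes. The steps were not of equal width, and that from 2.0 to 2.5 mm covers the widest gap in length. The step from 2.0 to 2.5 mm had 7500 called genes (1402 higher, 6098 lower) and that from 1.4 to 1.6 mm had 5402 (3359 higher, 2043 lower). The step from 1.0 to 1.2 mm had 2268 called genes, from 1.8 to 2.0 mm 1779, from 1.2 to 1.4 mm 1373, from 0.4 to 0.6 mm 1265, from 0.6 to 0.8 mm 1183, from 0.8 to 1.0 mm 539, and from 1.6 to 1.8 mm 293. Differences between the counts of steps were not tested. Quantile normalization gave 4963 genes from 2.0 to 2.5 mm and 5314 from 1.4 to 1.6 mm, so the order of these steps depended on the scaling. Fits on the 2 sizes alone gave 0 genes from 1.2 to 1.4 mm (limma, 2039 at an unadjusted p under 0.05), 842 from 1.0 to 1.2 mm, 750 from 0.4 to 0.6 mm, 293 from 0.8 to 1.0 mm and 493 from 1.6 to 1.8 mm. A pseudocount of 0.1 gave 122 genes from 1.6 to 1.8 mm. Single libraries moved several of the smaller counts by over 1.5 times. The step from 0.4 to 0.6 mm gave 832 genes without 0.4 mm replicate 2, and that from 1.0 to 1.2 mm gave 1366 without 1.2 mm replicate 3. The step from 1.2 to 1.4 mm gave 438 without 1.2 mm replicate 2 and 2348 without 1.2 mm replicate 3. The step from 0.8 to 1.0 mm gave 355, 301 and 976 genes without 0.8 mm replicates 1, 2 and 3, and 284 and 345 without 1.0 mm replicates 1 and 2. The step from 1.6 to 1.8 mm gave 163 and 107 genes without 1.6 mm replicates 2 and 3, and 99 without 1.8 mm replicate 2. Quantile normalization changed the share of higher genes from 49.1% to 62.0% at 1.2 mm against 1.0 mm, from 62.2% to 51.4% at 1.6 mm against 1.4 mm, and from 18.7% to 47.0% at 2.5 mm against 2.0 mm. Rescaling to TPM changed it to 64.4% at 1.2 mm against 1.0 mm, and from 56.5% to 41.0% at 1.4 mm against 1.2 mm.

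**Figure D2:**
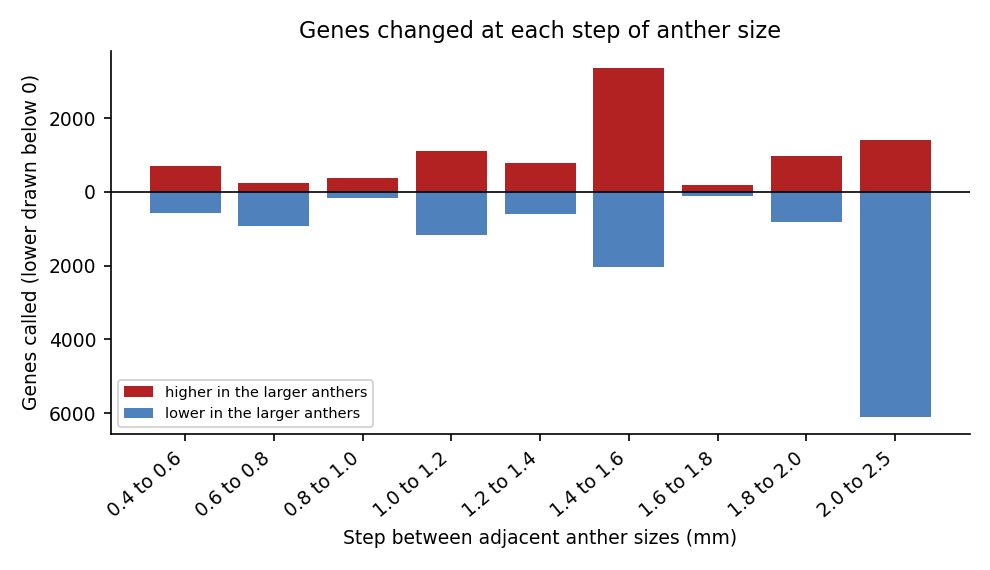
Bars give the number of genes called in limma at each step between adjacent anther lengths (horizontal axis, mm), with genes higher in the larger anthers above 0 and genes lower in them drawn below 0. The 2 tallest steps are 1.4 to 1.6 mm (3359 higher, 2043 lower) and 2.0 to 2.5 mm (1402 higher, 6098 lower), a balance that quantile normalization moved to 51.4% and 47.0% higher. The step from 2.0 to 2.5 mm covers the widest gap in length.

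In the small RNA libraries the most abundant entries were miR168a-5p, which targets the gene of an Argonaute protein, and miR166abcdj-3p, which targets genes of class III HD-ZIP transcription factors. Over all 30 libraries their means were 194499 and 140223 CPM. In edgeR (quasi-likelihood), 250 of 371 tested entries (67.4%) differed among the 10 labelled sizes at an adjusted p (Benjamini-Hochberg) under the limit of 0.05. The count was 112 without replicate 1 of every size and 164 without replicate 2. Of the 250, 57 were highest in libraries labelled 1.6 mm (names carrying 2.5 mm) and 41 in those labelled 1.8 mm (names carrying 0.4 mm).

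A pair of miRNA families triggers phased small RNAs in grass anthers. Counts of the miR2118 family, whose targets give the shorter class of reproductive phased small RNAs, summed over its 10 entries, were 61129 ± 9845, 56136 ± 12911 and 40417 ± 26777 CPM in libraries labelled 1.8, 2.0 and 2.5 mm (names carrying 0.4, 0.6 and 0.8 mm; mean ± SD, n = 3). They lay between 1774 ± 52.5, in libraries labelled 1.6 mm (names carrying 2.5 mm), and 12877 ± 10647, in those labelled 0.6 mm (names carrying 1.2 mm), in the other groups. Single libraries differed: replicates 1, 2 and 3 had 23630, 12660 and 2340 CPM in the group labelled 0.6 mm and 59121, 9744 and 52388 in that labelled 2.5 mm. The miR2275 family, whose targets give the longer class, had 18717 ± 1515 CPM in libraries labelled 1.8 mm (names carrying 0.4 mm), 65414 ± 17287 in those labelled 2.0 mm (0.6 mm), 66694 ± 36532 in those labelled 2.5 mm (0.8 mm), 76486 ± 53310 in those labelled 1.0 mm (1.6 mm) and 14859 ± 21243 in those labelled 1.4 mm (2.0 mm). In the last group replicates 1, 2 and 3 had 3846, 1383 and 39347 CPM, and in the group labelled 1.0 mm 97811, 115832 and 15814. These sums are a description, and the tests below are on single entries and lists.

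**Figure D3:**
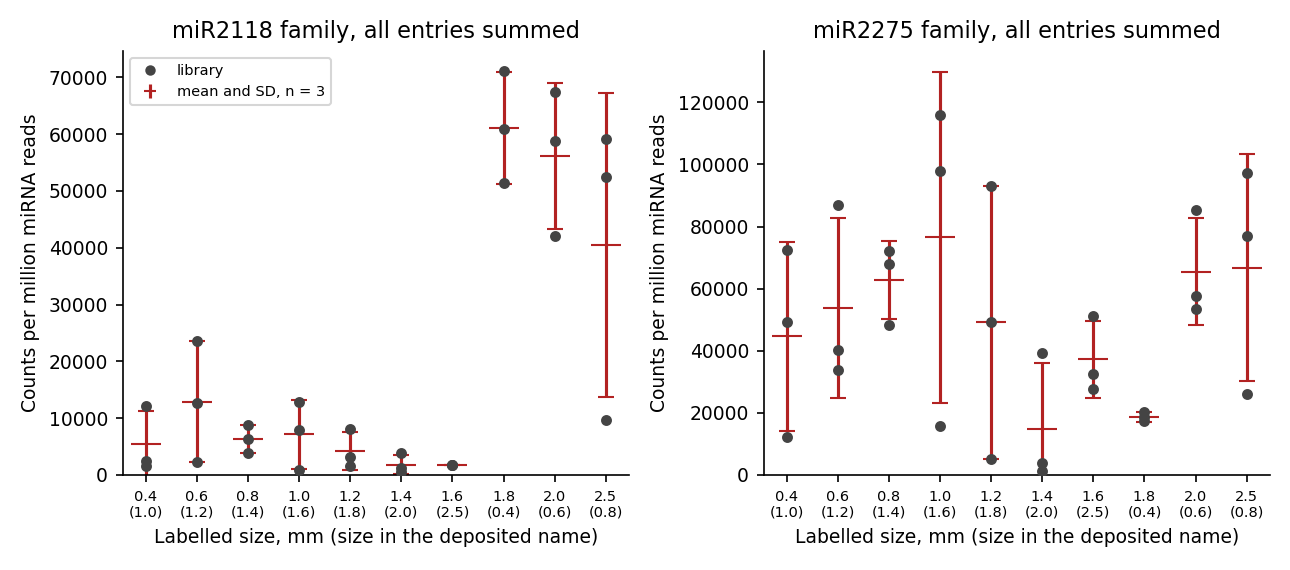
CPM (vertical axes) of the miR2118 family (left) and the miR2275 family (right) in each small RNA library (points), with the mean and SD of n = 3 (bars), by labelled anther length in mm and, in brackets, the size in the deposited name (horizontal axis). The miR2118 means are 61129, 56136 and 40417 in the groups labelled 1.8, 2.0 and 2.5 mm and at most 12877 in the other groups.

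Distances between the group mean profiles of small RNA were compared with those of mRNA to ask which order of sizes the small RNA groups follow. Over the 45 pairs of groups, Pearson's r was 0.120 (one-sided permutation p = 0.226) and Spearman's rho 0.189 (p = 0.118) with the labelled sizes. With the sizes in the deposited names r was 0.802 (permutation p = 2e-05) and rho 0.855 (p = 2e-05). Across the 10 rotations of the labels tested, the adjusted p (Benjamini-Hochberg) of r was 0.337 for the labels and 0.0002 for the deposited names, which ranked 6 and 1. Without 2.0 and 2.5 mm, which lay farthest out, r was 0.321 with the labels and 0.814 with the deposited names. With those sizes left out, 2 other rotations also gave 0.781 and 0.814. Each rotation leaves out the small RNA groups that it places at 2.0 and 2.5 mm. These values therefore rest on different small RNA groups and do not rank the rotations.

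**Figure D4:**
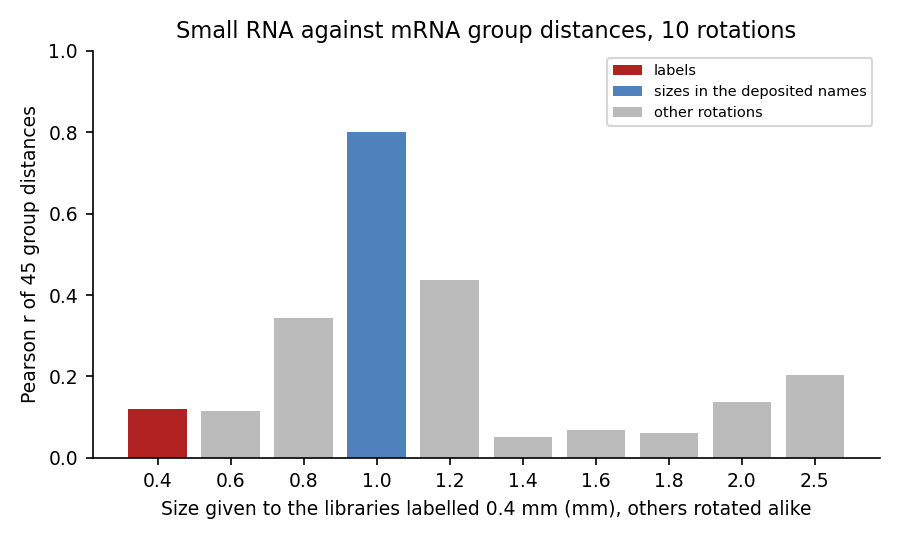
Bars give Pearson's r between the 45 distances among small RNA groups and those among mRNA groups (vertical axis) for each of the 10 rotations of the small RNA sizes, named by the size in mm given to the libraries labelled 0.4 mm (horizontal axis). The labels give 0.120 and the sizes in the deposited names 0.802, the highest of the 10.

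Comparing libraries labelled 1.0 mm with those labelled 0.4 mm (names carrying 1.6 and 1.0 mm), 44 of 371 miRNA entries changed, 15 higher and 29 lower. This balance depended on the processing: 34.1% were higher in edgeR, 53.5% in DESeq2, 59.0% with counts summed per family and 51.7% without the 4 libraries doubted for depth or for low correlation with the others. Several passenger strands of the miR166 family were among the falls: miR166b-5p went from 3791 ± 3913 to 51.5 ± 28.0 CPM (mean ± SD, n = 3; log2 fold change -6.14, SE 1.26, adjusted p = 7.21e-04 in edgeR). In the same family miR166ae-5p went from 1728 ± 1514 to 43.1 ± 24.7 (log2 fold change -5.45, SE 1.14, adjusted p = 8.49e-04) and miR166l-5p from 1193 ± 883 to 21.4 ± 22.9 (-5.22, SE 1.06, adjusted p = 6.62e-04). In all, 6 of its 14 tested members fell while 0 rose. Besides these they were miR166h-5p, miR166k-5p and miR166kl-3p, and the most abundant member, miR166abcdj-3p, was not called. Also lower were miR5837.2 (log2 fold change -5.19) and miR5539ab (-4.46). Among the rises, miR810b.2 went from 0 counts in the group to 241 ± 151 CPM, at least 18.0-fold higher by the floor of 3 counts over the group (adjusted p = 9.57e-04). Entry miR5149 went from 0 counts to 286 ± 257, at least 21.4-fold higher (adjusted p = 0.00388). Entry miR1865-3p went from 0 counts to 117 ± 112, at least 8.75-fold higher (adjusted p = 0.0237). These bounds pool the reads of the group labelled 0.4 mm and leave out the spread between libraries. Its replicates 1, 2 and 3 had floors of 53.9, 39.5 and 32.2 CPM. Levels of miR1865-5p went from 3.58 ± 6.2 to 411 ± 178, miR1428e-3p from 3.58 ± 6.2 to 861 ± 747, and miR164abf, which targets genes of NAC transcription factors, from 11.5 ± 10.8 to 633 ± 522 CPM. These last 3 had 1, 1 and 3 counts in the group labelled 0.4 mm, so no fold is given.

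The tables of that comparison differed in their reference set. All 3 libraries labelled 1.0 mm and the library labelled 0.4 mm replicate 3 had been counted against a reference set of another name, so within that set only 1 library stood against 3. Whether the name marks a batch is not known. With a model term for those 4 libraries 1 of the 44 entries remained called, and of the 36 with more than 3 counts in the lower group 29 kept their direction. In that fit the log2 fold change of miR166ae-5p was 2.24 (SE 1.5, adjusted p = 0.482) and that of miR166b-5p -0.52 (SE 1.29, adjusted p = 0.854). Those of miR166kl-3p, miR166h-5p, miR166k-5p and miR166l-5p were 1.43, -0.318, -1.20 and -2.25. The 8 entries with 3 counts or fewer in the lower group all kept their direction, and their median SE rose from 1.78 to 2.66. A fit on these 6 libraries alone called 0 entries in edgeR, with 39 of 183 at an unadjusted p under 0.05, and DESeq2 on all libraries called 71, of which 44 were shared. Without the library labelled 0.4 mm replicate 1 the count was 26. The call of miR1865-3p was lost without any of the libraries labelled 0.4 mm replicates 1, 2 or 3 or 1.0 mm replicate 1 (adjusted p = 0.078, 0.09, 0.0733 and 0.0925).

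By the lists fixed in advance, the phase-change miRNAs, which include miR156 and miR172, differed upwards as a list in that comparison (fry, median log2 fold change 0.84, adjusted p = 0.0394 over 30 list tests), with 2 of 13 members called higher, and 2 adjusted over the list alone. One was miR535-5p, which went from 558 ± 504 to 2974 ± 1744 CPM (log2 fold change 2.39, SE 0.793, adjusted p = 0.0442 in edgeR). Its call was lost with the term for the 4 libraries (adjusted p = 0.49), with the replicate block (0.0625), without TMM (0.0743), without the filter (0.117), in a fit on the 6 libraries alone (0.221), and without the libraries labelled 0.4 mm replicates 1 or 2 or 1.0 mm replicates 1, 2 or 3 (adjusted p = 0.227, 0.183, 0.0898, 0.158 and 0.0574). The list was not called with that term (adjusted p = 0.35), without TMM (0.252), without the filter (0.124), in a fit on the 6 libraries alone (0.379), or in any of the 6 fits that left out 1 library. Adjusted p there was 0.458, 0.236 and 0.182 without 0.4 mm replicates 1, 2 and 3, and 0.272, 0.408 and 0.126 without 1.0 mm replicates 1, 2 and 3. The median log2 fold change of the list was not smaller where its call was lost. It was 1.09 with the term, 0.946 without TMM, 1.03 without the filter and 0.905 on the 6 libraries alone. Without 1 library it ran from 0.887 to 1.16. Among the nutrient and copper miRNAs, miR395bdeghijklsmnpqry, whose family acts in sulfate supply, fell from 3880 ± 2657 to 443 ± 349 CPM (log2 fold change -2.80, SE 0.795, adjusted p = 0.017). That call was lost with the term (adjusted p = 0.402), without the filter (0.117), in the fit on the 6 libraries alone (0.296), and without 0.4 mm replicate 1 or 1.0 mm replicates 1 or 2 (0.286, 0.122 and 0.123). The other 9 lists were not called in that comparison: adjusted p was 0.996 for the miR2118 list, 0.466 for miR2275, 0.57 for miR390, 0.996 for miR159 with miR319, 0.0982 for the auxin list (0.00991 without the 4 doubted libraries), 0.778 for the meristem and leaf list, 0.632 for miR162 with miR168, 0.778 for nutrient and copper and 0.251 for miR444. By the fry test for change in either direction, which was not fixed in advance and for which no alternative was run, the meristem and leaf list had an adjusted p of 3.77e-05, with 14 of 36 members adjusted over the list alone.

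In libraries labelled 1.6 mm against those labelled 1.0 mm (names carrying 2.5 and 1.6 mm), 15 miRNA entries changed, 9 higher and 6 lower. DESeq2 called 30 (21 higher, 9 lower), and with counts summed per family 10 were called, of which 30.0% were higher, against 60.0% here. The miR393 family, which targets genes of auxin receptors, stood out: miR393a went from 941 ± 191 to 23342 ± 10372 CPM (mean ± SD, n = 3; log2 fold change 4.67, SE 0.814, adjusted p = 6.36e-04 in edgeR). Counts of miR393b-5p went from 1065 ± 210 to 23259 ± 10429 (4.49, SE 0.798, adjusted p = 6.36e-04). Summed over its 3 entries the family held 62818 ± 25631 CPM in the group labelled 1.6 mm and between 1299 ± 60.8 and 8352 ± 7145 in the other 9 groups. Rises were also called for miR396ab-5p (1279 ± 465 to 14849 ± 8251), miR396e-5p (15196 ± 10829 to 88211 ± 41005), miR397a, which targets laccase genes (48.6 ± 42.6 to 375 ± 51.5), miR5485 (3.50 ± 6.06 to 151 ± 54.4) and miR160f-3p (2 counts in the group labelled 1.0 mm, 1.17 ± 2.02, to 134 ± 65.0). Falls were called for miR171c-5p, from 1222 ± 569 to 90.2 ± 35.1 (log2 fold change -3.57, SE 0.706, adjusted p = 0.0022), miR171b (5414 ± 3954 to 681 ± 409), miR171i-5p (69.6 ± 53.6 to 2.71 ± 4.69, with 2 counts), miR2275g (672 ± 360 to 59.3 ± 30.6) and miR2275h (172 ± 125 to 14.0 ± 6.04).

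The libraries labelled 1.0 mm were all counted against the other reference set and those labelled 1.6 mm were not, so no comparison within one set could be had. A term for that set, which could be fitted only through the group labelled 0.4 mm, gave 33 called entries (4 higher, 29 lower) of which 2 were shared with the 15. In it miR393a had a log2 fold change of 3.44 (adjusted p = 0.0638), miR393b-5p 3.46 (0.0621), miR396e-5p -1.65 (0.43) and miR397a -0.48 (0.966). Leaving out 1 library gave 8 called entries without 1.0 mm replicate 1, 8 without 1.0 mm replicate 2, and 6, 5 and 4 without 1.6 mm replicates 1, 2 and 3. The calls of miR393a, miR393b-5p and miR171c-5p held in all 6 of these fits, and those of the other entries named were lost in 2 to 6 of them. Without TMM the calls of miR171b, miR396e-5p, miR397a and miR2275h were lost (adjusted p = 0.071, 0.071, 0.085 and 0.0547). Without the filter those of miR171b, miR396e-5p, miR5485 and miR2275h were lost (0.15, 0.115, 0.0535 and 0.0846). A fit on the 6 libraries alone lost those of miR171b and miR5485 (0.087 and 0.0748). It called 8 entries, 6 higher and 2 lower, so other falls named above were lost or not tested in it. In the lists, nutrient and copper miRNAs differed upwards (fry, median log2 fold change 0.73, adjusted p = 0.0339), with 2 of 14 members called, both of the miR397 family, and 3 adjusted over the list alone. That list turned downwards with the term for the 4 libraries (-0.25, adjusted p = 0.797), and was not called without TMM (0.252), without the filter (0.236), or without 1.0 mm replicates 1, 2 or 3 (0.408, 0.408 and 0.222) or 1.6 mm replicates 1 or 2 (0.262 and 0.236). The other adjusted p values were 0.178 for miR2118, 0.137 for miR2275, 0.388 for miR390, 0.996 for phase change, 0.534 for miR159 with miR319, 0.107 for auxin (0.0205 without the 4 doubted libraries), 0.996 for meristem and leaf, 0.0982 for miR162 with miR168 (0.0267 without them and 0.0499 in a fit on the 6 libraries alone) and 0.993 for miR444. The phase-change list had a median of 0.26 and a mean of -0.10 with a downward test, the meristem and leaf list a median of 0.04 and a mean of -0.03 with an upward test, and the miR444 list a median of 0.05 and a mean of -0.14 with an upward test. For change in either direction the adjusted p was 9.82e-06 for meristem and leaf (5 of 36 members over the list alone) and 3.77e-05 for auxin (5 of 17).

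Of the 3 comparisons, that of libraries labelled 2.5 and 1.6 mm (names carrying 0.8 and 2.5 mm) covers the widest gap in length, by label and by name. By the names its direction is reversed, with the smaller anthers in the libraries labelled 2.5 mm, so rises and falls with growth would swap. That comparison had the largest number of miRNA changes, with 140 entries, 71 higher and 69 lower in libraries labelled 2.5 mm. All 10 miR2118 entries were higher there, with log2 fold changes from 2.81 to 5.98, and the list was called (fry, adjusted p = 0.00324; 10 adjusted over the list alone). The most abundant, miR2118fjmhk, went from 774 ± 104 to 14341 ± 9359 CPM (mean ± SD, n = 3; log2 fold change 3.52, SE 1.02, adjusted p = 0.00754 in edgeR). Counts of miR2118bncq went from 170 ± 66.2 to 6377 ± 4467 (4.55, SE 0.991, adjusted p = 7.19e-04) and miR2118d from 123 ± 35.4 to 4327 ± 2674 (4.48, SE 0.842, adjusted p = 1.25e-04). In the miR2275 family 8 of 12 entries were higher and 0 lower, with 8 adjusted over the list alone, while the list was not called (adjusted p = 0.0921; called at 0.021 without the 4 doubted libraries and at 0.00812 in a fit on the 6 libraries alone). Its most abundant entries were not called: miR2275i had 20173 ± 8338 and 28034 ± 18348 CPM, miR2275c 9875 ± 5843 and 25752 ± 11183, and miR2275d 6560 ± 3680 and 3477 ± 2189. In a fit on the 6 libraries alone miR2275c was called higher (adjusted p = 0.0429), and DESeq2 called miR2275d lower (0.0187). All 10 miR2118 entries were also called higher by DESeq2 and without TMM, and for miR2275 DESeq2 called 6 higher and 2 lower. The miR2118 list was called in all 12 alternatives run for it, with adjusted p between 6.2e-04 and 0.0164.

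Conserved families had members going both ways in the libraries labelled 2.5 mm. Of the tested entries, 5 of 14 in miR166 were called higher and 1 lower, 4 of 9 in miR171 higher and 2 lower, and 2 of 5 in miR159 and 2 of 3 in miR319 higher. By contrast 2 of 6 in miR156, 2 of 7 in miR167, 3 of 3 in miR393 and 2 of 2 in miR397 were called lower in edgeR. DESeq2 called 3, 4, 3 and 2 lower, and without TMM 1, 2, 3 and 2 were lower and 1 of miR167 was higher. For miR166, miR171, miR159 and miR319 DESeq2 called 3, 2, 1 and 1 higher and 2, 3, 0 and 0 lower. Without TMM 5, 4, 2 and 1 were higher and 1, 1, 0 and 0 lower. Entry miR156adei, which targets genes of SPL transcription factors, went from 61937 ± 3848 to 4881 ± 1581 CPM (mean ± SD, n = 3; log2 fold change -3.84, SE 0.669, adjusted p = 5.08e-05 in edgeR). Entry miR393b-5p went from 23259 ± 10429 to 701 ± 353 (-5.49, SE 0.841, adjusted p = 8.29e-06). Values of miR167dehi-5p, which targets genes of auxin response factors, went from 64365 ± 10423 to 8717 ± 4108 (-3.30, SE 0.741, adjusted p = 9.08e-04). All 3 miR393 entries were lower under TMM, under DESeq2 and without TMM. Called falls of nutrient and copper miRNAs included miR397a, from 375 ± 51.5 to 72.8 ± 57.3 CPM (-3.18, SE 0.884, adjusted p = 0.00546), and miR399j, of a family that acts in phosphate supply, from 639 ± 120 to 82.8 ± 108 (-2.88, SE 1.10, adjusted p = 0.0375). Entry miR529b went from 247 ± 65.1 to 16.1 ± 14.0 (-3.29, SE 0.953, adjusted p = 0.0075). The call of miR397a was lost without 2.5 mm replicate 2 (adjusted p = 0.11), and that of miR529b without 1.6 mm replicate 2 or 2.5 mm replicate 3 (0.0569 and 0.0575). That of miR399j was lost without TMM (0.0816), without the filter (0.0742), without the 4 doubted libraries (0.0759) and in all 6 fits that left out 1 library: 0.159, 0.126 and 0.095 without 1.6 mm replicates 1, 2 and 3, and 0.12, 0.219 and 0.0606 without 2.5 mm replicates 1, 2 and 3.

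Single entries with the largest changes in that comparison included miR166l-5p, from 8.04 ± 0.31 to 2031 ± 783 CPM (mean ± SD, n = 3; log2 fold change 7.82, SE 1.20, adjusted p = 8.29e-06 in edgeR), and miR5496, from 77.5 ± 14.0 to 8766 ± 5368 (6.30, SE 0.752, adjusted p = 6.28e-07). Also higher were miR5544 (log2 fold change 6.32), miR5837.2 (6.07) and miR171i-5p (2 counts in the group labelled 1.6 mm, to 401 ± 192 CPM). The largest falls, by label, included miR810b.1, from 27927 ± 4787 to 180 ± 41.2 (-7.11, SE 0.929, adjusted p = 1.93e-06). Of the others, miR5485 and miR440 had 151 ± 54.4 and 92.1 ± 18.9 CPM in the group labelled 1.6 mm. Both had 0 counts in the group labelled 2.5 mm, at least 36.9-fold and 22.5-fold lower by the floor of 3 counts over its pooled reads. In that group replicates 1, 2 and 3 had floors of 399, 5.65 and 15.4 CPM, so replicate 1 alone could not show either fall. Entries miR1428e-3p and miR810b.2 had 1268 ± 488 and 983 ± 362 CPM in the group labelled 1.6 mm and 1 and 3 counts in that labelled 2.5 mm. Higher values of miR159a.1, which targets genes of GAMYB transcription factors, 68141 ± 81176 against 18064 ± 3762 (log2 fold change 2.45, adjusted p = 0.0388), and of miR319a-3p.2-3p, 243 ± 260 against 49.4 ± 13.8 (2.86, adjusted p = 0.0324), rested on the library labelled 2.5 mm replicate 2, without which the log2 fold changes were 0.01 (adjusted p = 0.993) and 0.38 (0.863). The calls of miR159a.1 and miR319a-3p.2-3p were also lost without 1.6 mm replicate 1 (adjusted p = 0.0626 and 0.05) or replicate 3 (0.0564 and 0.0548), and that of miR319a-3p.2-3p without replicate 2 (0.0585) or without TMM (0.0521). Both were lost with the replicate block (0.109 and 0.0962) and in DESeq2 (log2 fold change 0.78, adjusted p = 0.444, and 1.21, adjusted p = 0.358). That of miR159a.1 was lost in a fit on the 6 libraries alone (0.0503).

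Neither group of that comparison held a library of the other reference set. The median log2 fold change of all tested entries was -0.87 under TMM, -0.632 without TMM and -2.22 under DESeq2, which called 221 entries (52 higher, 169 lower), so directions of single entries are relative to that shift. Beside that shift, the auxin list had a median of -0.83 (fry, adjusted p = 0.0167), with 7 of 17 members called lower and 11 adjusted over the list alone, so its median was no lower than that of all entries. Its call was lost without TMM (adjusted p = 0.252), without the filter (0.124) and in each fit without 1 of the 6 libraries: 0.262, 0.236 and 0.0723 without 1.6 mm replicates 1, 2 and 3, and 0.0649, 0.26 and 0.0642 without 2.5 mm replicates 1, 2 and 3. The phase-change list had a median of -1.44 (adjusted p = 0.0234), with 4 of 13 members called lower, 4 adjusted over the list alone. That call was lost without TMM (0.252), without the filter (0.138), without the 4 doubted libraries (0.129), in a fit on the 6 libraries alone (0.0528), without 1.6 mm replicates 1 or 2 (0.372 and 0.236) and without 2.5 mm replicates 1, 2 or 3 (0.0668, 0.198 and 0.0642). The nutrient and copper list had a median of -1.55 (adjusted p = 0.0339), with 5 of 14 members called lower and 1 higher, 8 adjusted over the list alone. It was not called without TMM (0.36), without the filter (0.124), in a fit on the 6 libraries alone (0.124), or without 1 of the 6 libraries: 0.366, 0.264 and 0.0974 without 1.6 mm replicates 1, 2 and 3, and 0.0649, 0.552 and 0.0738 without 2.5 mm replicates 1, 2 and 3. The other lists were not called, with adjusted p of 0.688 for miR390, 0.178 for miR159 with miR319 (0.0224 without the 4 doubted libraries), 0.518 for meristem and leaf (0.047 without them), 0.0921 for miR162 with miR168 and 0.459 for miR444. For change in either direction the adjusted p of the meristem and leaf list was 1.8e-09, with 10 members called higher, 7 lower and 18 of 36 adjusted over the list alone.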

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

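Among the tests here, the rank of the labelled order was chosen before its result was seen, and those on the 3 small RNA libraries and on the late fall of mRNA were chosen after.

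Most reads in the deposited small RNA tables were assigned to no miRNA and fall outside the comparisons: a median of 98.9% over the 26 libraries that list them, with a range from 97.5% to 99.3%. The files give no sequence for them, so their origin was not analysed here.

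The small RNA groups did not follow the mRNA groups in the labelled order, which ranked 6 of the 10 rotations by correlation of group distances (r = 0.120). The rotation given by the deposited names ranked 1 (r = 0.802). A rotation of the small RNA titles against the true sizes is a candidate explanation, which this test could have ruled out and did not. No biological explanation was tested. Without 2.0 and 2.5 mm another rotation also gave 0.814, but on other small RNA groups, so that value does not rank the rotations. If the names, as read here, are right, the high miR2118 counts would belong to anthers of 0.4 to 0.8 mm, which stays a hypothesis.

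The libraries labelled 1.2 mm replicate 2 and 1.4 mm replicates 1 and 2 (names carrying 1.8 and 2.0 mm) correlated less with the others, with medians from 0.535 to 0.642 against at least 0.658 for the other 27. They were not shallow, since the lowest total of the 3 was 393315, above the median of 195159 of the others. Leaving out the 2 leading miRNAs, miR1856 and miR168a-5p, left their highest median at 0.615, equal to the lowest of the others. It raised none of the 3 medians, which went from 0.639 to 0.615, from 0.642 to 0.611 and from 0.535 to 0.491. These values argue against those 2 miRNAs as the cause of the low correlations of these 3 libraries. With labelled sizes other than 1.2 and 1.4 mm their highest correlations were 0.802 for 1.4 mm replicate 1 and 0.727 and 0.677 for 1.2 mm replicate 2 and 1.4 mm replicate 2. The other libraries reached at least 0.773 with their best size. The library labelled 1.2 mm replicate 2 correlated at 0.895 with the libraries labelled 1.4 mm and at 0.653 with its own size. Other libraries also lay closer to another label. The library labelled 1.4 mm replicate 3 correlated at 0.964 with those labelled 1.6 mm and at 0.728 with replicates 1 and 2 of its own. Every library labelled 0.4, 1.2 or 2.5 mm correlated best with another label, the own mean being taken without the library itself. The groups labelled 0.4 and 2.5 mm are part of the comparisons. Other abundant miRNAs, which were not left out, and a wrong label stay open, and no biological explanation was tested.

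More genes were lower than higher at 2.5 than at 1.6 mm. Different FPKM sums between the sizes do not account for it: after rescaling to TPM 81.7% of the called genes were lower. The 100 most abundant genes would shift the others by -0.232 on the log2 scale, less than the median shift of -0.522, so they are too few to explain it alone, while the 1000 most abundant would give -0.577. A concentration of FPKM in about that many genes stays open, as does a biological difference between the sizes, which cannot be separated from it on relative values. Quantile normalization removes such a shift by construction and decides nothing.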

How the results depend on the processing

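Alternatives chosen only after the data were seen were the rescaling to TPM, the removal of doubted libraries, and those of the lists, of the size of highest mean and of the label check. The cause of the changes below was not tested unless one is given. The 12 values of gene IDs kept direction and call under all alternatives run for them. These IDs were picked for the largest changes in the same libraries, so this says little about the other called genes. Not run were DESeq2 for mRNA, since there are no counts, and TPM supplied by the authors, since only FPKM were given (TPM rescaled from FPKM were run). Also not run were the other miRNA table, which is identical, and merging of entries with equal counts, of which there are none. Without the 4 libraries of the other reference set no library labelled 1.0 mm is left, so only the last comparison and the test over all sizes could be had. Whether replicate numbers pair the libraries was not settled. Deviations from the group mean correlated at a median of -0.0022 for mRNA and 0.0242 for small RNA between libraries of the same number. Of 135 such pairs, 25 for mRNA and 35 for small RNA were above 0.1, with highest values of 0.342 and 0.792. On average 14 and 15 of the 30 libraries correlated best with their own number. With the replicate block 3931, 6017 and 10203 genes and 40, 14 and 143 miRNAs were called in the 3 comparisons. Depth limits rare miRNAs most in the library labelled 2.5 mm replicate 1, where 3 counts are 399 CPM.

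With a pseudocount of 0.1 the step from 1.6 to 1.8 mm gave 122 genes. With quantile normalization 4882 genes were highest at 2.5 mm and the step from 2.0 to 2.5 mm gave 4963. Fits on the compared sizes alone, which have fewer libraries to estimate the spread, gave 750 genes for 0.4 to 0.6 mm and 293 for 0.8 to 1.0 mm. They gave 842 for 1.0 to 1.2 mm, 0 for 1.2 to 1.4 mm (limma, 2039 at an unadjusted p under 0.05) and 493 for 1.6 to 1.8 mm. For miRNA they gave 0 for labelled 1.0 against 0.4 mm (edgeR, 39 unadjusted, against 71 in DESeq2 on all libraries) and 8 for 1.6 against 1.0 mm. Adjusted p alone gave 6387 genes for 1.0 against 0.4 mm, 9084 for 1.6 against 1.0 mm, 3619 for 1.0 to 1.2 mm, 8663 for 1.4 to 1.6 mm, 2766 for 1.8 to 2.0 mm and 12797 for 2.0 to 2.5 mm, as the fold limit was dropped. DESeq2 gave 71, 30 and 221 miRNAs in the 3 comparisons. For 1.6 against 1.0 mm 9 miRNAs were called without TMM and 8 without the filter. Of the 30 list tests over the 3 comparisons, 1 was called in each of these fits in place of 6. Without the 4 doubted libraries 11 of the 30 list tests were called. The term for the 4 libraries of the other reference set gave 1 miRNA for 1.0 against 0.4 mm and 33 for 1.6 against 1.0 mm, and turned miR166ae-5p to 2.24 in the first, and miR396e-5p to -1.65, miR397a to -0.48 and the nutrient and copper list to -0.25 in the second.

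Leaving out 1 replicate of every size gave 19167 to 21664 genes over all sizes, 2271 to 2432 highest at 2.5 mm, and 112 to 267 miRNAs. Leaving out 1 library gave 3477 to 4026 genes for 1.0 against 0.4 mm, 5722 to 6005 for 1.6 against 1.0 mm and 8532 to 12140 for 2.5 against 1.6 mm. By step it gave 832 to 1435, 850 to 1187, 284 to 976, 1366 to 3259, 438 to 2348, 4585 to 6531, 99 to 301, 1376 to 1821 and 5239 to 10218 genes. For miRNA it gave 26 to 65, 4 to 14 and 105 to 120.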

Other observations

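The counts of the comparisons restated here and the model term for the 4 libraries were chosen before the data were examined, and the tests of the mix, of neighbouring IDs and of other splits were chosen after the results were seen.

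Some miRNA families of the fixed lists had courses that the comparisons of the report do not cover. The miR528 family had 7845 ± 4049 CPM in libraries labelled 0.6 mm (names carrying 1.2 mm), 6051 ± 2081 in those labelled 2.0 mm (0.6 mm) and 340 ± 165 in those labelled 1.8 mm (0.4 mm; mean ± SD, n = 3). The miR166 family had 422952 ± 56793 CPM in libraries labelled 0.6 mm (1.2 mm) and 124255 ± 95015 in those labelled 1.4 mm (2.0 mm). The miR167 family had 134128 ± 44327 in libraries labelled 0.8 mm (1.4 mm) and 15084 ± 1224 in those labelled 1.8 mm (0.4 mm), and the miR390 family, which triggers trans-acting small RNAs, had 10521 ± 373 and 5172 ± 1188 in the same groups. These differences were not tested. The miRNA miR1856, which is on none of the lists and was picked after its values were seen, held 66.0% of the miRNA reads in the library labelled 1.4 mm replicate 2. In the library labelled 1.0 mm replicate 3, which is part of 2 of the comparisons, miR168a-5p held 65.8%.

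In the mRNA library of 1.4 mm replicate 1, 1 gene held 15.6% of the FPKM. The mRNA library of 2.5 mm replicate 3 lay between the 2.0 mm libraries and the other 2.5 mm libraries for 94.6% of the 3200 genes that differed between these by at least 2 log2 units. A mix of both kinds of RNA at one ratio may be proposed as an explanation, but it would place rising and falling genes equally far along. The falling genes lay at 54.5% of the way and the rising genes at 15.8%, a difference of 38.8 points. The same measure ran from -26.4 to 20.9 points in the 6 libraries of 1.6 and 2.0 mm (95% prediction interval for another library -41.2 to 49.5). None of these libraries reached 38.8 points, but the interval, drawn from only 6 values, holds it, so such a mix stays open. Those libraries lay at 77.8% to 128% of the way for rising genes, unlike 2.5 mm replicate 3, which limits them as a measure of its spread.

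Genes with adjacent ID numbers reached their highest mean at the same size in 18.3% of 14731 pairs, against a mean of 12.8% and a highest value of 13.7% when sizes were permuted within chromosomes (p = 0.0001, the smallest that 10000 permutations can give). A candidate explanation is shared regulation or duplication of neighbouring genes, which the files cannot tell apart, and genes whose reads are shared between close copies stay open as well.

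Other splits of the same libraries were counted for each test across genes. For the tests over all sizes 1 of 100 splits, the real one, gave as many calls, with 23980 genes against at most 4874 in the others and 250 miRNAs against at most 65. That share is the smallest that 100 splits can give and lies under 0.05, so chance alone is unlikely for both. The miRNA splits do not separate size from the reference set, since all 3 libraries labelled 1.0 mm were of the other set. For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and in each 1 of the 10, the real one, gave as many. Real and highest other counts were 3932 and 2 for 1.0 against 0.4 mm, 6013 and 0 for 1.6 against 1.0 mm and 10187 and 2927 for 2.5 against 1.6 mm. For the steps they were 1265 and 64, 1183 and 16, 539 and 95, 2268 and 238, 1373 and 560, 5402 and 4, 293 and 4, 1779 and 1, and 7500 and 4263, in order of size. The splits behind 2927 and 4263 put 2.5 mm replicate 3 with the smaller size. For miRNA they were 44 and 41 for labelled 1.0 against 0.4 mm, 15 and 0 for 1.6 against 1.0 mm and 140 and 0 for 2.5 against 1.6 mm. The split that gave 41 put the library labelled 0.4 mm replicate 3 with 1.0 mm replicates 1 and 3, which are 3 of the 4 libraries of the other reference set, and with a model term for these 4 the real comparison called 1 entry. Of the 36 called entries with more than 3 counts in the lower group 29 kept their direction with the term, and their median absolute log2 fold change of 3.52 (median SE 0.81) became 1.44 along the same direction (median SE 0.936). The 8 entries with 3 counts or fewer kept their direction while their median SE rose from 1.78 to 2.66, so for these the ended calls do not show that the reference set explains the rises.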
